A study of Mus musculus with 12 samples.

How the data were processed

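Total RNA from the cerebellum of 12 mice aged 6 weeks was measured on expression arrays, 1 array per mouse. The mice carried a Sca6 knockin allele with 11 or 118 glutamine codons (MPI 11Q/11Q and MPI 118Q/118Q in the labels) or were wild type littermates of either line, on a C57BL/6 background. This gives 4 groups of 3 arrays: wild type and knockin of the 11Q line, and wild type and knockin of the 118Q line. Per the labels, RNA was extracted with RNeasy columns, was treated with DNase, had an RNA integrity number above 5.0 in every sample, and was labelled with biotin by a one-cycle kit.

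The deposited values are log2 expression per probe set, made by the authors with RMA, whose version and settings are not given in the sources used here. The median of an array over all 45101 probe sets lay between 2.21 and 2.38. Sorted values differed between arrays, so the arrays do not share 1 identical distribution. Most dim probe sets lie lower than RMA usually places them, so the values are used as relative levels on a log2 scale. No further normalization was applied. The number of arrays, 3 in each group, limits the precision; the median standard error of a difference between groups was 0.139 log2 units for a single effect and 0.197 for a difference of effects.

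Probe sets were given gene symbols from the array annotation: 34958 had 1 symbol, 932 had several and 9211 had none listed. The 40% of probe sets with the lowest mean over the 12 arrays were removed (log2 mean under 1.58), which left 27060. For each symbol the probe set with the highest mean was kept, which gave 12671 genes, of which 5988 had another probe set above the filter. Gene order and gene span, the distance from a gene's start to its end, were taken from an annotation of the mouse assembly GRCm38.p6 and existed for 12645 of these genes.

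The design, the gene lists, the rule for naming genes and the alternatives, except those named as added, were fixed before the data were examined. A group-means model over all 12 arrays was fitted to each gene with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom and 4.61 prior degrees of freedom. The comparisons were the knockin against its littermates in each line, the difference between these effects, knockin against knockin and wild type against wild type. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes, two-sided. Errors of fold changes are standard errors from this model, and errors of group means are standard deviations of 3 arrays.

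Lists of genes for cell types, pathways and the neighbourhood of Cacna1a were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 38 lists with at least 5 measured members. A list of sex-linked genes was described and not tested. Camera with an estimated correlation and fry, both in limma, were run beside it; fry's p tests whether a list's genes move, on balance, one way. In each list, genes were also adjusted over the list alone.

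The genes named in the text followed a rule. Cacna1a was named first. For each knockin effect and for their difference, the 10 genes with the largest rise and the 10 with the largest fall were named among those called with all 3 knockin arrays beyond all 3 littermate arrays. Where fewer passed, genes with the smallest unadjusted p filled the number. Up to 4 members of each list were named by the smallest p in the 118Q effect, and up to 5 genes in each direction for the remaining comparisons. Clones and predicted genes were passed over when naming.

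Alternatives planned beforehand were no filter, removal of the lowest 60%, the mean of a gene's probe sets, probe sets tested one by one, arrays centred on their median, quantile normalization, an intensity trend in the variance, array weights, a fit of only the groups compared, the replicate number within a line as a block, an adjusted p below 0.1, an unadjusted p below 0.05 with a fold of at least 1.5, and leaving out each array in turn. Alternatives added after seeing the data were removal of a trend with gene span within each array, Ttr as covariate, the 18S ribosomal RNA signal as covariate, and leaving out wild type replicate 3 of both lines. A planned covariate for Xist was not run, since Xist spanned 0.665 log2 units over the arrays and the plan needed a span of 3.

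The steps were tested on simulated data with 12671 genes and the same groups, with noise drawn independently for each gene and array. The simulated arrays did not differ in quality and their genes were not correlated, so the rates below need not hold for the real arrays. For the 118Q effect the simulation recovered 29.9% of genes changed by 0.5 log2 units, 83.6% of those changed by 1 and all 66 changed by 2, with 7 false calls. For the difference of effects it recovered 5.97%, 59.7% and 97.0% with 5 false calls, and for knockin against knockin 28.4%, 80.6% and 98.5% with 4. The 11Q effect and wild type against wild type, simulated with no changed gene, gave 0 false calls by limma.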

Results

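Cerebellar RNA was profiled in 12 mice at 6 weeks of age, with 3 arrays in each of 4 groups: wild type and knockin mice of the 11Q line and of the 118Q line. The knockin allele is in Cacna1a, the gene for the pore-forming subunit of the P/Q-type calcium channel, which Purkinje cells express strongly. The 118Q allele codes for a long glutamine tract and the 11Q allele for a tract of normal length. The title of the series names an early inflammatory response and Purkinje cell loss as its subject. Pairs of arrays correlated at 0.980 to 0.995 across probe sets, and the brightest probe set of an array read at least 11.8. Eif2s3y, a gene of the Y chromosome, read 5.44 to 6.44 in every array, and Xist, the RNA of the inactive X chromosome, 1.00 to 1.66.

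Cacna1a itself read 5.94 ± 0.35 (SD, n = 3) in wild type and 5.61 ± 0.09 in knockin mice of the 118Q line. Its difference was -0.34 ± 0.15 (SE; adjusted p = 0.264) and turned to 0.06 with the 18S signal as covariate, an alternative added after seeing the data. It was -0.54 without wild type replicate 2 and -0.21 without wild type replicate 3. The other Cacna1a probe sets above the filter differed by -0.14 and 0.17. In the 11Q line it differed by -0.07 (adjusted p = 0.954).

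Comparing the 118Q knockin with its littermates asks what the knocked-in sequence with the expanded repeat changes in its own line. By itself this comparison cannot separate the repeat from the rest of the knocked-in sequence. Fgf14, a regulator of voltage-gated sodium channels that is mutated in an inherited ataxia, fell 3.11-fold, by 1.64 ± 0.20 on the log2 scale (SE, 3 against 3 arrays; adjusted p = 0.00521). Of the other Fgf14 probe sets above the filter, 1 differed by -1.74 ± 0.26 and 1 by -0.11 ± 0.18. Slc1a6, the glutamate transporter of Purkinje cells, fell by 1.13 ± 0.20, and Atp2a2, the calcium pump of the endoplasmic reticulum, by 0.69 ± 0.12. Trem2, a receptor of microglia, rose by 0.77 ± 0.13, and Rps18, a ribosomal protein, by 0.63 ± 0.11. In all, limma called 24 genes, 10 higher and 14 lower, and in each the 3 knockin arrays lay beyond the 3 littermate arrays. Such separation was found in 22.4% of all genes, where chance gives 10%.

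Among the other genes that rose in the 118Q knockin were Cenpb, a centromere protein (1.00 ± 0.15, adjusted p = 0.0317), Myl6, a myosin light chain (0.77), Hddc2 (0.66), Fbxo2, a subunit of a ubiquitin ligase for glycoproteins (0.64), and Il20rb, an interleukin receptor subunit (0.61). Those that fell included Tuba8, an alpha tubulin (-1.20 ± 0.15, adjusted p = 0.00533), Stk17b (-0.99), Kcnq1ot1, a long noncoding RNA (-0.98), Flt1, a receptor for vascular endothelial growth factor (-0.95), Mtss1, an actin-binding protein (-0.81), Dpp10, a partner of voltage-gated potassium channels (-0.77), and Ptchd4 (-0.69). Their adjusted p-values were at most 0.0465. Rps27 (0.58, adjusted p = 0.0527), Tyrobp, the signalling partner of Trem2 (1.03, adjusted p = 0.0549), and Churc1 (0.57, adjusted p = 0.0564) did not pass. The smallest adjusted p, 0.00333, belonged to clones, of which 6330415B21Rik fell by 1.68 and is named after its values were seen. In the 11Q line these named genes differed by -0.30 (Hddc2) to 0.28 (Myl6), and none passed.

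The number of genes called in the 118Q knockin depended on single arrays. It was 6, 44 and 7 without wild type replicate 1, 2 and 3, and 707, 5 and 4 without knockin replicate 1, 2 and 3, against 24 with all arrays; 6, 18, 6, 24, 5 and 4 of the 24 genes were among them. Fgf14 was called in each of these fits, but not in a fit of only the groups compared (adjusted p = 0.139) or with the 18S signal as covariate (-0.92, adjusted p = 0.652), and Tuba8 missed without knockin replicate 3 (adjusted p = 0.0551). Slc1a6, Atp2a2, Trem2 and Rps18 each missed without wild type replicate 1 or 3 or knockin replicate 2 or 3 (adjusted p = 0.0893 to 0.219). Slc1a6 and Rps18 also missed without wild type replicate 2 (0.0597 and 0.0542). The share of higher genes, 10 of 24, became 13 of 48 with arrays centred on their median and 13 of 43 with quantile normalization. A fit of only the 6 arrays compared, a fit with the 18S signal as covariate, and a fit with the gene span trend removed gave 0, 0 and 7 genes by limma. With all arrays 2365 genes had an unadjusted p below 0.05, 1516 higher and 849 lower, where chance gives 634 for independent genes. Other splits of the 6 arrays compared gave 204 to 1689 such genes. Splits that mixed the wild types of both lines, with no knockin allele involved, gave 144 to 2435. Those with wild type replicates 3 of both lines on the same side gave 1165 to 2435, and the others 144 to 593.

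**Figure D1:**
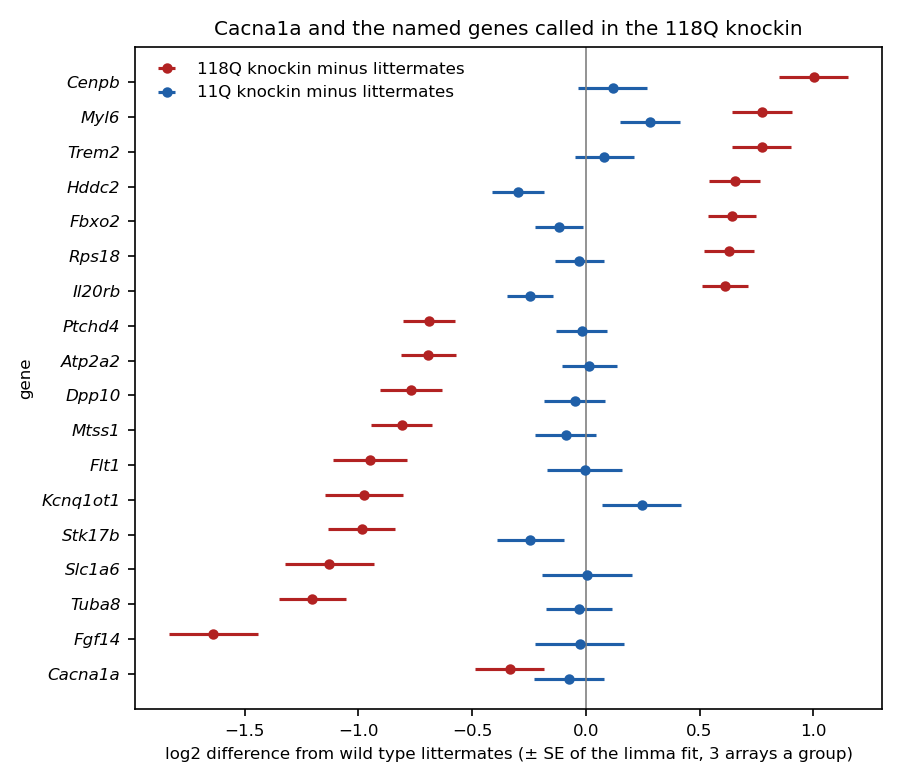
Log2 difference from wild type littermates (x axis) for Cacna1a and the 17 named genes called in the 118Q knockin (y axis). Points are estimates and bars standard errors of the limma fit, 3 arrays a group, with the 118Q line in red and the 11Q line in blue; Fgf14 lies at -1.64 in the 118Q line and at -0.03 in the 11Q line.

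Purkinje cell genes were lower in the 118Q knockin. The 33 measured Purkinje cell markers had a median of -0.46, with 29 below 0, and fell as a list (adjusted p = 5.14e-14; adjusted p = 0.139 with an estimated correlation). Of these, 1 gene, Slc1a6, was called over all genes and 17 were lower when adjusted over the list alone. Plxdc1 (-1.08, adjusted p = 0.0572), Dner, a Notch ligand of Purkinje cells (-1.04, adjusted p = 0.066), and Car8, which binds the inositol trisphosphate receptor (-0.65, adjusted p = 0.0689), did not pass over all genes. The per-array medians of the list, as deviations from the mean of all arrays, were -0.07, -0.50 and -0.45 in the 118Q knockin and 0.07 to 0.20 in its littermates. Pcp2, a bright Purkinje marker named after its value was seen, differed by 0.14 and did not pass.

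Mouse ataxia genes expressed in Purkinje cells fell as a list, with a median of -0.34 and 17 of 18 below 0 (adjusted p = 1.67e-12; adjusted p = 0.139 with an estimated correlation). Fgf14 and Slc1a6 were called, 10 genes were lower when adjusted over the list alone, and Itpka, which phosphorylates inositol trisphosphate, differed by -0.50 (adjusted p = 0.0689). Zebrin-related Purkinje genes also fell (median -0.21, 10 of 12 below 0, adjusted p = 0.000126; adjusted p = 0.176 with an estimated correlation), with 3 lower when adjusted over the list alone; Plcb3 differed by -0.52. Voltage-gated calcium channel subunits fell by a median of 0.14 (11 of 15 below 0, adjusted p = 0.00194; adjusted p = 0.139 with an estimated correlation). Of those, 2 were lower when adjusted over the list alone, and Cacna2d2 (-0.75) and Cacna1g, a T-type channel (-0.58), did not pass over all genes. This last call ended when the trend with gene span was removed (median -0.01, adjusted p = 0.491). By fry, all 4 of these lists moved on balance lower (adjusted p = 0.0159, 0.0066, 0.0307 and 0.0258).

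Microglial genes were higher in the 118Q knockin. The 31 measured microglia markers rose as a list, with a median of 0.34 and 28 above 0 (adjusted p = 4.58e-05; adjusted p = 0.176 with an estimated correlation; fry adjusted p = 0.0128). Trem2 was called, 9 markers were higher when adjusted over the list alone, and Sparc (0.53) and Fcgr3, an Fc receptor (0.69), did not pass over all genes. Disease-associated microglia genes rose by a median of 0.23 (19 of 22 above 0, adjusted p = 0.00226; adjusted p = 0.343 with an estimated correlation; fry adjusted p = 0.0464), 7 of them when adjusted over the list alone. Cd68, a lysosomal protein of phagocytes, differed by 1.08 and Cd52 by 0.92, both without passing. Without knockin replicate 1 this second list did not pass (adjusted p = 0.161). The per-array medians of the microglia list were 0.46, 0.22 and 0.40 in the knockin and -0.04 to 0.11 in its littermates.

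Lists for inflammation did not pass in the 118Q knockin, but many of their genes were not tested in the reported fit. Measured were 12 of 35 cytokine and NF-kB genes, 19 of 32 Toll-like receptor and MyD88 genes and 7 of 18 alternative activation genes. The other lists had 21 of 35 (complement), 26 of 39 (reactive astrocyte) and 33 of 40 (interferon). These results say nothing of the genes that were not measured. Inflammatory cytokines and NF-kB targets had a median of -0.00 over 12 measured members (adjusted p = 0.9), and Tnfaip2 differed by 0.42. The Toll-like receptor and MyD88 pathway had a median of 0.10 over 19 members (adjusted p = 0.393), and Cd14, a co-receptor for lipopolysaccharide, differed by 0.42. Reactive astrocyte genes (median -0.02, adjusted p = 0.372), interferon-stimulated genes (-0.05, adjusted p = 0.13), antigen presentation and complement (0.11, adjusted p = 0.828) and alternative macrophage activation genes (0.05, adjusted p = 0.828) did not pass. In the complement list 3 genes were higher and 1 lower when adjusted over the list alone, and C1qb, a subunit of complement C1q that microglia make, differed by 0.73 (adjusted p = 0.115). None of these 6 lists moved on balance one way by fry (adjusted p = 0.136 or more), and the complement list passed fry's test for change in either direction (adjusted p = 0.00241).

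Genes of protein synthesis and energy metabolism were higher. All 31 measured cytosolic ribosomal proteins lay above 0, with a median of 0.32 (adjusted p = 1.67e-12; adjusted p = 0.243 with an estimated correlation; fry adjusted p = 0.0128), and 21 were higher when adjusted over the list alone, among them Rps14 (0.49) and Rps19 (0.50). Oxidative phosphorylation subunits rose by a median of 0.19 (38 of 50 above 0, adjusted p = 0.00194; adjusted p = 0.444 with an estimated correlation; fry adjusted p = 0.0283), 2 of them when adjusted over the list alone; Ndufa6, a subunit of complex I, differed by 0.44. Antioxidant and NRF2 targets rose by a median of 0.17 (20 of 24 above 0, adjusted p = 0.0101; adjusted p = 0.204 with an estimated correlation; fry adjusted p = 0.0066), 1 of them when adjusted over the list alone; Gpx4, which reduces lipid peroxides, differed by 0.44. The last list did not pass without knockin replicate 1 (adjusted p = 0.0816), and with the gene span trend removed neither it (median 0.10, adjusted p = 0.101) nor oxidative phosphorylation (0.07, adjusted p = 0.562) passed.

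Lists of vessel, interneuron and meningeal markers passed on the lower side by camera at the preset correlation, and of these only the vessel list by fry. Endothelial and mural cell markers fell by a median of 0.36 (22 of 24 below 0, adjusted p = 2.68e-10; adjusted p = 0.176 with an estimated correlation; fry adjusted p = 0.0283). Flt1 was called, 6 were lower when adjusted over the list alone, and Acta2, smooth muscle actin (-1.14), and Abcb1a, a transporter of the blood-brain barrier (-0.96), did not pass over all genes. Cerebellar interneuron markers fell by a median of 0.30 (14 of 17 below 0, adjusted p = 0.000111; adjusted p = 0.204 with an estimated correlation; fry adjusted p = 0.104), with 0 called by limma, 0 when adjusted over the list alone and 7 at an unadjusted p below 0.05. Gad1 (-0.79) and Slc32a1 (-0.74), which make and load the transmitter GABA, are also in the Purkinje list; without knockin replicate 2 they differed by -0.48 and -0.46. Meningeal fibroblast markers fell by a median of 0.20 (16 of 19 below 0, adjusted p = 0.00355; adjusted p = 0.343 with an estimated correlation; fry adjusted p = 0.241), 0 of them by limma when adjusted over the list alone and 2 at an unadjusted p below 0.05. Lum, a matrix proteoglycan, differed by -0.49.

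Glucocorticoid-responsive, immediate early, chaperone and synaptic lists also passed by camera at the preset correlation, but none of them by fry or with an estimated correlation. All 18 measured glucocorticoid-responsive genes lay above 0, with a median of 0.40 (adjusted p = 0.00194; adjusted p = 0.394 with an estimated correlation; fry adjusted p = 0.11), 0 by limma when adjusted over the list alone and 6 at an unadjusted p below 0.05. Per1, a clock gene that glucocorticoids induce, and Arrdc2 each differed by 0.76, and by 0.40 and 0.48 without wild type replicate 3. Immediate early genes rose by a median of 0.38 (20 of 25 above 0, adjusted p = 0.0195; adjusted p = 0.451 with an estimated correlation; fry adjusted p = 0.139), 1 of them when adjusted over the list alone. Gadd45b differed by 0.58 and Nr4a1 by 0.73 (0.47 without wild type replicate 3). Cytosolic chaperones fell by a median of 0.14 (22 of 28 below 0, adjusted p = 0.000274; adjusted p = 0.343 with an estimated correlation; fry adjusted p = 0.172), 3 of them when adjusted over the list alone. Hspa4 differed by -0.62. Synaptic vesicle and transmission genes had a median of -0.04 (24 of 37 below 0, adjusted p = 0.0195; adjusted p = 0.394 with an estimated correlation; fry adjusted p = 0.442), 0 of them by limma when adjusted over the list alone and 7 at an unadjusted p below 0.05. Pclo, a scaffold of the presynaptic terminal, differed by -0.69. Single arrays ended 3 of these calls: glucocorticoid genes without knockin replicate 1 (adjusted p = 0.0728), immediate early genes without wild type replicate 3 (0.311) or knockin replicate 1 (0.173), and synaptic genes without wild type replicate 1 (0.0702), wild type replicate 2 (0.156) or knockin replicate 2 (0.0741). The synaptic median turned to 0.02 without wild type replicate 2, and that call also ended with the gene span trend removed (median 0.0051, adjusted p = 0.703); among random lists matched on gene span and mean expression its median lay at percentile 67.6.

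Measures of RNA and hybridisation also separated the 118Q knockin from its littermates. The 18S ribosomal RNA signal was 8.80 ± 0.37 (SD, n = 3) against 9.92 ± 0.35, with no overlap, and an exact permutation test gave p = 0.1, two-sided, the smallest that 3 against 3 arrays allow. The phe spike-in control was 0.69 higher, also with no overlap. The dap, lys and thr spike-in controls were 0.35, 0.50 and 0.49 higher, with ranges that overlapped. Across genes within an array, the Spearman correlation between a gene's deviation and its span averaged -0.293 in the 118Q knockin and 0.036 in its littermates; genes are not independent replicates. With the 18S signal as covariate, 6 of the 16 lists passed, and 10 did not. Of those that passed, the medians of the Purkinje (-0.15), ataxia (-0.17), chaperone (-0.078) and calcium channel lists (-0.080, adjusted p = 0.0271) were nearer to 0 than without the covariate, and those of the disease-associated microglia (0.37) and synaptic lists (-0.088, adjusted p = 0.0126) farther from it. The adjusted p was 0.00636 for the other 4. Of those that did not, the median of the microglia list was 0.34 as before (adjusted p = 0.367), and those of the immediate early (0.36, adjusted p = 0.438), glucocorticoid (0.34, adjusted p = 0.502), antioxidant (0.14, adjusted p = 0.466), ribosomal (0.19, adjusted p = 0.149) and oxidative phosphorylation lists (0.10, adjusted p = 0.577) stayed above 0. The zebrin-related (0.023, adjusted p = 0.577), interneuron (0.059, adjusted p = 0.34), endothelial (0.061, adjusted p = 0.34) and meningeal lists (0.13, adjusted p = 0.903) turned. The median standard error over genes went from 0.139 to 0.264, so a lost call does not show that the 18S difference made the change. Gad1, Slc32a1, Abcb1a, Pclo and Per1 then changed sign (0.08, 0.02, 0.13, 0.01 and -0.27). The covariate and the removal of the span trend were chosen after seeing the data.

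**Figure D2:**
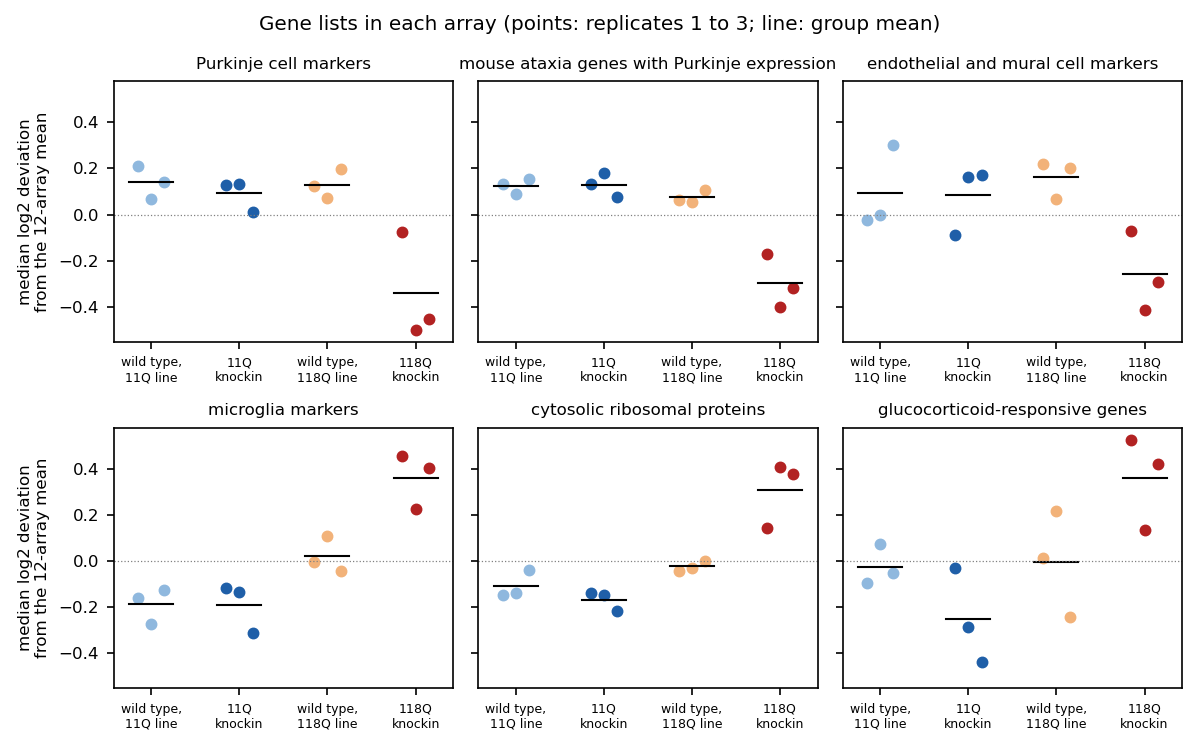
Median log2 deviation of 6 gene lists from the mean of all 12 arrays (y axis) in each array, by group (x axis). Points are replicates and lines group means; the 118Q knockin arrays lie between -0.50 and -0.07 for Purkinje cell markers and between 0.22 and 0.46 for microglia markers.

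**Figure D3:**
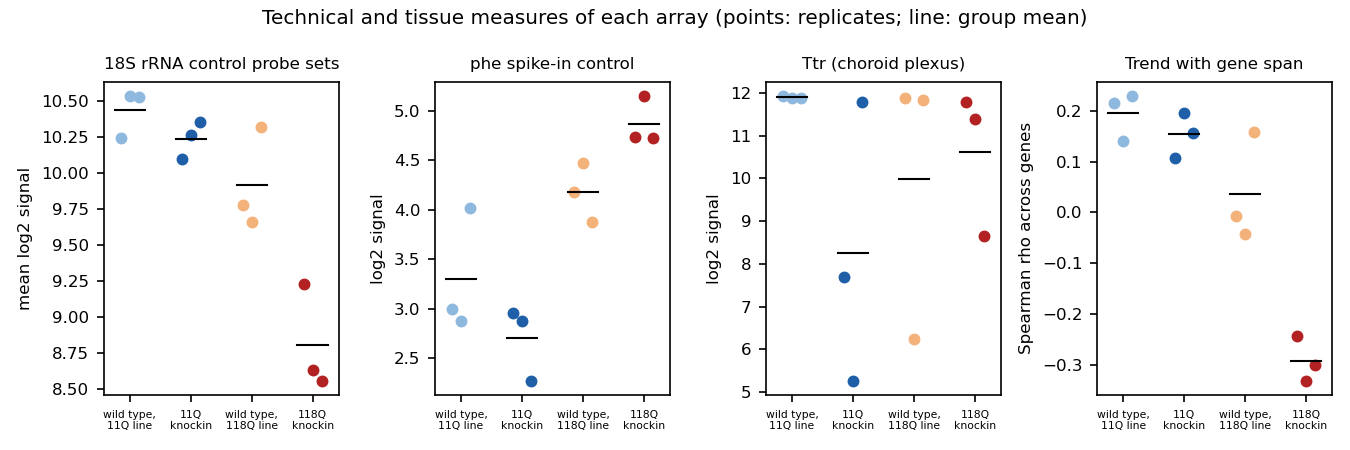
Signal of the 18S control probe sets, of the phe spike-in control and of Ttr (log2), and the Spearman correlation across genes between deviation and gene span, in each array by group. Points are replicates and lines group means; the 18S mean is 8.80 in the 118Q knockin and 9.92 in its littermates.

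Comparing the 11Q knockin with its littermates asks what the knocked-in sequence does with a repeat of normal length. Choroid plexus markers were lower, with a median of -1.85 and all 18 measured members below 0, and the list fell (adjusted p = 9.31e-13; adjusted p = 0.563 with an estimated correlation). This followed single mice: Ttr, the abundant transport protein of choroid plexus, read 7.68, 5.26 and 11.8 in the knockin and 11.9 in each littermate. The median deviation of the 17 other markers was -1.35, -1.59 and 0.47 in the knockin and 0.46 to 1.17 in its littermates. With Ttr, itself a member of the list, as covariate, the list did not pass (median -0.22, adjusted p = 0.194), which says little, since the fit uses a member of the list. This covariate was added after seeing the data. No single gene passed: limma called 0 genes, 536 had an unadjusted p below 0.05 where chance gives 634, and the smallest adjusted p was 0.419. Group ranges were apart in 10.4% of genes, where chance gives 10%.

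The genes nearest to passing in the 11Q line lay partly on chromosome 8, which carries Cacna1a. Higher without passing were Comp, a cartilage matrix protein (2.60 ± 0.49, adjusted p = 0.419), Mau2, a cohesin loader (1.24, adjusted p = 0.419), Ocel1 (1.08), Slc25a42, a mitochondrial carrier (0.83), Rasip1 (0.55), Olfml2b (0.54), Ifitm3 (0.49), Dcdc2b (0.49), Izumo1r (0.38) and Plppr3 (0.37). Lower without passing were Il33, an alarmin cytokine (-1.26, adjusted p = 0.419), Lpcat2 (-1.12), Gadd45gip1 (-0.97), Mri1 (-0.75), Pnma2 (-0.75), Zfp869 (-0.68), Nt5e (-0.61), Tpd52l1 (-0.60), Zfp961 (-0.60) and Arhgap18 (-0.54). Other probe sets above the filter differed in the 11Q line by 0.10, 0.19 and 0.47 for Mau2, 0.29 for Gadd45gip1, 0.23 for Nt5e and 0.06 for Dcdc2b. In the 118Q line Mau2 differed by 0.50 and Slc25a42 by 0.58 (adjusted p = 0.211 and 0.149), and Il33 by -0.42 (adjusted p = 0.318). Mri1 (0.37), Tpd52l1 (0.29) and Ifitm3 (-0.23) lay on the other side there, and Zfp869 and Gadd45gip1 differed by -0.04 each; none of these passed. Genes adjoining Cacna1a on chromosome 8 had a median of 0.17 in the 118Q knockin (adjusted p = 0.0962; fry adjusted p = 0.0283), with Farsa at 0.40.

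Camera passed 6 other lists in the 11Q line, none of them with an estimated correlation (adjusted p = 0.563 or more) or by fry (adjusted p = 0.782 or more), and none with a gene that passed by limma when adjusted over the list alone. Interferon-stimulated genes had a median of 0.23 (28 of 33 above 0, 4 at an unadjusted p below 0.05, adjusted p = 9.44e-08), which ended without knockin replicate 1 (median 0.08, adjusted p = 0.436). The remaining lists were oligodendrocyte and myelin genes (median -0.18, adjusted p = 0.0319), granule cell markers (0.06, adjusted p = 0.0319), synaptic genes (0.05, adjusted p = 0.0319), blood cell genes (0.26, adjusted p = 0.0319) and reactive astrocyte genes (0.08, adjusted p = 0.0418). Leaving out a single array ended each of them. The oligodendrocyte list missed without wild type replicate 2 (0.283) or 3 (0.205) or knockin replicate 1 (median -0.03, adjusted p = 0.796). The granule list missed without wild type replicate 3 (0.266) or knockin replicate 2 (0.0662). The synaptic list missed without wild type replicate 2 (0.0545) or 3 (0.477) or knockin replicate 2 (0.0751) or 3 (0.0503). The blood list missed without wild type replicate 1 (0.109) or 3 (0.0751) or knockin replicate 3 (median 0.05, adjusted p = 0.185). The reactive astrocyte list missed without wild type replicate 1 (0.129) or 2 (0.255) or knockin replicate 1 (0.0884) or 2 (0.0662).

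**Figure D4:**
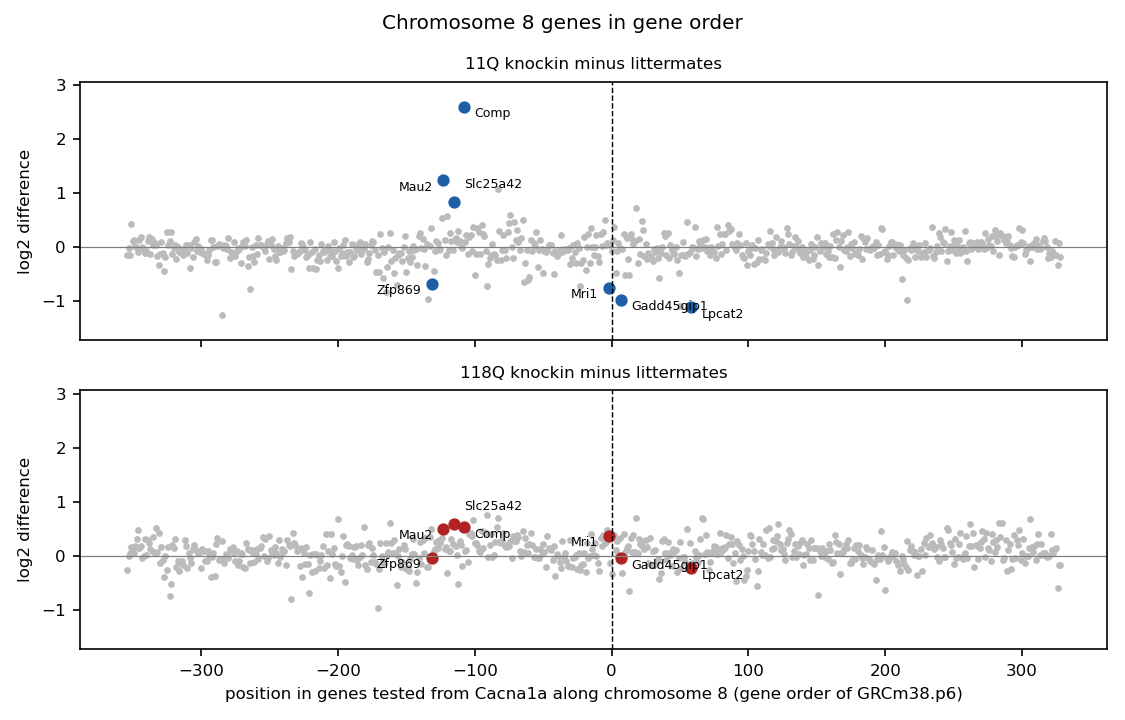
Log2 difference from littermates (y axis) of genes on chromosome 8 in gene order, as the number of tested genes from Cacna1a (x axis; gene order of GRCm38.p6), for the 11Q line above and the 118Q line below. Each point is a gene, and coloured points are the 7 genes at an unadjusted p below 0.001 in the 11Q line, from Zfp869 at -131 to Lpcat2 at 58.

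The difference between both knockin effects asks whether the effect depends on the length of the repeat. Ataxia genes moved lower in the 118Q than in the 11Q line (median of the difference -0.39, 17 of 18 below 0, adjusted p = 3.94e-13; adjusted p = 0.0844 with an estimated correlation; fry adjusted p = 0.0223). Purkinje cell markers differed the same way (-0.43, 28 of 33 below 0, adjusted p = 3.87e-13; adjusted p = 0.163 with an estimated correlation; fry adjusted p = 0.0908), and microglia markers the other way (0.40, 27 of 31 above 0, adjusted p = 0.000543; adjusted p = 0.214 with an estimated correlation; fry adjusted p = 0.0586; median 0.44 and adjusted p = 0.362 with the 18S covariate). All 31 ribosomal proteins were on the higher side (0.39, adjusted p = 5.65e-12; adjusted p = 0.214 with an estimated correlation; fry adjusted p = 0.0471). When adjusted over the list alone, 6 ataxia genes and 5 Purkinje markers were lower, and 2 microglia markers and 12 ribosomal proteins higher. In all, 20 of 38 lists passed, 9 higher and 11 lower, but 0 with an estimated correlation and 3 by fry.

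No single gene passed the test of the difference: limma called 0 genes, 1392 had an unadjusted p below 0.05 where chance gives 634, and the smallest adjusted p was 0.132. Nearest on the higher side were Fhit, a tumour suppressor (1.39), Olfml1 (1.20), Mri1 (1.12), Arid5a (0.97), Hddc2 (0.95, adjusted p = 0.132), Kif1c, a kinesin motor (0.87), Il20rb (0.86, adjusted p = 0.132), Nckap1l, an actin regulator of blood cells (0.85), Use1 (0.78) and Fbxo2 (0.76). Nearest on the lower side were Fgf14 (-1.61 ± 0.28, adjusted p = 0.134), Kcnq1ot1 (-1.22), Tuba8 (-1.17), Fn1, fibronectin (-1.10), Vmn1r58 (-0.93), Ptpn14 (-0.74), Pou5f2 (-0.74), Atp2a2 (-0.71), Ptchd4 (-0.67) and Ank2, an ankyrin (-0.60). Leaving out wild type replicate 2 of the 118Q line gave 4 genes and leaving out knockin replicate 1 gave 12.

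The 118Q knockin compared directly with the 11Q knockin is open to differences between the lines, and it gave 1733 called genes, 1277 higher and 456 lower, with groups apart in 38.1% of genes against 10% by chance. H2-Bl (2.17), Zfp874a (2.07), Nr4a3, a nuclear receptor induced by activity (1.86), Cxcl14, a chemokine (1.67), and Npas4, an activity-regulated transcription factor (1.64), were higher. Mid1 (-2.47), F2r, the thrombin receptor (-2.23), Fgf14 (-1.98 ± 0.20, adjusted p = 0.000862), St6galnac3 (-1.98) and H2-K1, a class I histocompatibility gene (-1.86), were lower. Cacna1a was lower by 0.68 ± 0.15 (adjusted p = 0.0162). It also read lower in the wild types of the 118Q line (5.54 to 6.19) than in those of the 11Q line (6.25 to 6.48), with no knockin allele. Camera passed 18 lists and fry 18, with 14 in common and 0 with an estimated correlation; 26 of 31 ribosomal proteins and 10 of 31 microglia markers were called higher and 12 of 33 Purkinje markers lower. The count was 0 by limma with the 18S signal as covariate, where Nr4a3 (-0.08) and F2r (0.47) changed sign, and 832 with the gene span trend removed. It was 721, 712 and 607 without 11Q knockin replicate 1, 2 and 3, and 624 and 319 without 118Q knockin replicate 2 and 3. Single arrays ended 5 of the named calls. Nr4a3, F2r and H2-K1 missed without 11Q knockin replicate 1, 2 or 3 or 118Q knockin replicate 2 or 3 (adjusted p = 0.0502 to 0.112). Zfp874a missed without 11Q knockin replicate 2 or 3 or 118Q knockin replicate 2 or 3 (0.0617 to 0.0706), and Npas4 without 11Q knockin replicate 1 or 3 or 118Q knockin replicate 2 or 3 (0.0525 to 0.0712). H2-K1 was -1.08 without 118Q knockin replicate 3.

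Wild type mice of both lines, compared as a control without any knockin allele, showed 0 called genes by limma, with 378 at an unadjusted p below 0.05 where chance gives 634, and groups apart in 6.44% of genes against 10% by chance; without wild type replicate 3 of the 11Q line or replicate 1 of the 118Q line 1 gene was called. Nearest on the higher side in the 118Q line were Cpne8 (0.87), Itih2 (0.62), Slc6a13, a GABA transporter (0.51), Ddr2, a collagen receptor (0.47), and Cpne6 (0.38). Nearest on the lower side were Soga3 (-0.73), Rmst, a long noncoding RNA (-0.71, adjusted p = 0.387), Eml6 (-0.65), Prex2 (-0.65) and Taf15 (-0.56). Camera nevertheless passed 12 lists here, and fry and camera with an estimated correlation (adjusted p = 0.251 or more) passed 0. Among them were meningeal fibroblast markers (0.23, adjusted p = 4.34e-06), microglia markers (0.15, adjusted p = 0.000175), ribosomal proteins (0.10, adjusted p = 0.000374) and choroid plexus markers (-0.88, adjusted p = 0.000175).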

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

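The tests of the gene span trend, of an even loss of Purkinje cell RNA, of choroid plexus tissue and of the 11Q genotype, the count of splits at an unadjusted p, and the splits for lists in knockin against knockin and wild type against wild type were chosen only after the results were seen, and the 18S covariate was added after seeing the data with its test written before its result.

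Purkinje cell markers, microglia markers and ribosomal proteins stood out because their knockin effects differed between the lines by camera: the median of the 118Q effect minus the 11Q effect was -0.43, 0.40 and 0.39 (log2). With an estimated correlation none of the 3 differences passed (adjusted p = 0.163, 0.214 and 0.214), and by fry only that of the ribosomal proteins did (adjusted p = 0.0908, 0.0586 and 0.0471). Among 10000 random lists matched on gene span and mean expression, the 118Q medians lay at percentile 0 for Purkinje markers, 100 for microglia markers and 100 for ribosomal proteins. The matched medians were -0.01, 0.08 and 0.16, so genes of like span and expression typically moved less than these lists. The draws take genes as independent, so the percentiles overstate how rare such medians are. Choroid plexus markers, which did not pass by camera in the 118Q effect, also lay at percentile 0. The percentiles therefore do not decide whether a trend with gene span is the whole cause. The 10 brightest Purkinje markers did not fall evenly: 4, Pcp4, Pcp2, Rgs8 and Gng13, had a 95% interval wholly above the list's median of -0.46. The interval of 1, Dner, lay wholly below it. Pcp2 and Calb1, about equally bright (10.5 and 10.6), differed by 0.14 and -0.76. The measured differences are thus not the same in every marker. The trend with gene span was left in these values, so they cannot separate an uneven loss from an even loss combined with that trend. Whether a loss of Purkinje cell RNA contributes stays open. The list also holds markers that interneurons share, such as Gad1 and Slc32a1, which need not fall alike. A difference in RNA handling may contribute and cannot be told apart from the genotype for the Purkinje list: with the 18S signal as covariate its median was -0.15 (adjusted p = 0.00636; the 118Q call also has adjusted p = 0.139 with an estimated correlation and 0.0159 by fry), the median standard error over genes went from 0.139 to 0.264, and the 18S ranges of 8.56 to 9.23 in the 118Q knockin and 9.66 to 10.3 in its littermates do not overlap. The microglia (median 0.34, adjusted p = 0.367) and ribosomal lists (0.19, adjusted p = 0.149) did not pass by camera with that covariate. For them too a difference in RNA handling cannot be told apart from the genotype. The expanded repeat itself, the biological explanation the design names, stays open.

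Choroid plexus markers stood out with a median difference between the knockin effects of 1.46. This difference missed the test without 11Q knockin replicate 2 (median 1.07, adjusted p = 0.0809), 118Q wild type replicate 2 (0.70, adjusted p = 0.341) or 118Q knockin replicate 1 (1.07, adjusted p = 0.136). It turned with Ttr, itself a member of the list, as covariate (median -0.14, adjusted p = 0.0238). With an estimated correlation it did not pass (adjusted p = 0.666), nor by fry (0.394). Ttr was low in single mice of several groups: 7.68 and 5.26 in the 11Q knockin, 6.25 in a wild type of the 118Q line and 8.66 in a 118Q knockin, against about 11.9 in the wild types of the 11Q line. Ttr at such levels lies near the brightest probe set of an array, which read at least 11.8, so it cannot show that mice are alike. The 11Q genotype as the whole cause is argued against by the 17 other choroid plexus markers, whose median deviation was over 3 SD below the mean of the 11Q wild types in 2 of the 6 mice of the 118Q line (-1.60 in a wild type and -1.40 in a knockin, against 0.46 to 1.17 in the 11Q wild types). A part played by the genotype within the 11Q line stays open. Choroid plexus tissue kept in some dissections may contribute: within groups, 10 of the 17 other measured choroid plexus markers (58.8%) followed Ttr at an adjusted p below 0.05, against 9 of 12653 other genes (0.0711%); 2 of the 17 are also in another list. That share lies between the bounds set for the test, under 50% and over 80%, so this explanation stays open.

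Other neuronal lists differed between the lines by camera, and none of the 20 differing lists passed with an estimated correlation. Mouse ataxia genes differed by a median of -0.39, zebrin-related Purkinje genes by -0.18, voltage-gated calcium channel subunits by -0.15 and cerebellar interneuron markers by -0.25. With the gene span trend removed the calcium channel list did not pass (median -0.10, adjusted p = 0.0715), and with the 18S covariate the zebrin-related list turned (0.07, adjusted p = 0.697) and the interneuron list did not pass (-0.07, adjusted p = 0.147). Synaptic genes differed by -0.12 and granule cell markers by -0.0607, the latter without passing with the 18S covariate (median -0.0761, adjusted p = 0.116). Among lists of other cells, endothelial and mural cell markers differed by -0.42 and meningeal fibroblast markers by -0.19, neither of which passed with the 18S covariate (medians -0.13 and -0.012, adjusted p = 0.0572 and 0.471). Oligodendrocyte and myelin genes differed by 0.38, a call that ended without 11Q knockin replicate 1 (median 0.21, adjusted p = 0.0816) or 118Q wild type replicate 3 (0.18, adjusted p = 0.414). It also ended with array weights (median 0.14, adjusted p = 0.895) or with the 18S covariate (0.13, adjusted p = 0.857). Disease-associated microglia genes differed by 0.25, which ended without 11Q wild type replicate 1 (0.0591), 11Q knockin replicate 2 (0.0506) or 118Q wild type replicate 3 (0.194). It also ended without 118Q knockin replicate 1 (median 0.11, adjusted p = 0.458), with the lowest 60% removed (0.09, adjusted p = 0.578) or with array weights (0.13, adjusted p = 0.177). Interferon-stimulated genes differed by -0.28, which ended without 11Q knockin replicate 1 (median 0.02, adjusted p = 0.0816) or with array weights (0.0695). Reactive astrocyte genes differed by -0.0655, which ended without 11Q wild type replicate 2 (0.0503), 11Q knockin replicate 1 (0.0579), 118Q wild type replicate 1 (0.0773) or 118Q knockin replicate 2 (0.072) or 3 (0.0625), with the lowest 60% removed (0.484), with quantile normalization (0.0654) or with the 18S covariate (median 0.10, adjusted p = 0.572).

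Among pathways, glucocorticoid-responsive genes differed by 0.56, which ended with the 18S covariate (median 0.52, adjusted p = 0.117). Oxidative phosphorylation subunits differed by 0.21, which ended with the gene span trend removed (median 0.0648, adjusted p = 0.602) or with the 18S covariate (0.13, adjusted p = 0.471). Immediate early genes differed by 0.38, which ended without 11Q wild type replicate 3 (adjusted p = 0.073), 118Q wild type replicate 3 (0.189) or 118Q knockin replicate 1 (0.14), with array weights (0.476) or with the 18S covariate (median 0.52, adjusted p = 0.201). Antioxidant and NRF2 targets differed by 0.22, which ended without 118Q wild type replicate 3 (0.0531) or 118Q knockin replicate 1 (0.0716), with the gene span trend removed (median 0.0808, adjusted p = 0.0916) or with the 18S covariate (median 0.18, adjusted p = 0.344). Without wild type replicate 3 of both lines the oligodendrocyte (adjusted p = 0.767), disease-associated microglia (0.144) and immediate early (0.611) differences did not pass.

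Probe sets with no single gene name, which no comparison used, held 344 of the 605 probe sets called in the 118Q knockin when 27002 probe sets were tested, 21 higher and 323 lower; 29.1% of the 4234 unnamed probe sets had an unadjusted p below 0.05, against 3643 of the 22768 named ones. The phe spike-in control, also outside the comparisons, was 0.69 higher in the 118Q knockin than in its littermates.

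Other splits of the same arrays were counted for every test across genes or lists. For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. For the 118Q effect the real split gave 24 genes and the highest other 0, with as many in 1 of 10 splits; for its lists the real split gave 16 and the highest other 17, with as many in 4 of 10. For the 11Q effect the real split gave 0 genes by limma (536 at an unadjusted p below 0.05) and the highest other 1, with as many in 10 of 10; for its lists it gave 7 and the highest other 13, with as many in 5 of 10. Knockin against knockin gave 1733 genes and the highest other 0, with as many in 1 of 10 splits, and 18 lists against 18, with as many in 2 of 10. The real split of wild type against wild type gave 0 genes by limma (378 at an unadjusted p below 0.05) and the highest other 0, with as many in 10 of 10, and 12 lists against 13, with as many in 2 of 10. For the difference between the effects 100 splits were drawn. The real split gave 0 genes by limma and the highest other 10; since every split gives at least 0, as many in 100 of 100 says nothing of chance. Chance cannot be excluded for its genes at an unadjusted p below 0.05, 1392 in the real split against 1699 in the highest other, with as many in 7 of 100. Lists of the difference at the preset correlation numbered 20 in the real split against 24 in the highest other, with as many in 2 of 100. This share is under 0.05, but drawn splits that kept the 118Q groups and reassigned only 11Q mice also gave 14 to 18 lists. The count therefore does not show by itself that the effect depends on repeat length. Of the 20 lists of the real split, 0 passed with an estimated correlation and 3 by fry.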

How the results depend on the processing

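The gene span trend, Ttr and 18S covariates and the fit without wild type replicate 3 of both lines were chosen only after the results were seen, and the other alternatives were planned. Counts of genes and lists stayed within 1.5 times the reported count in 128 combinations of result and alternative and moved further in 53; of the named genes' values 2047 kept their direction and side of the threshold, 193 lost the call, 139 gained it and 9 turned. The cause of these moves was not tested, and the cause was not tested for any value below.

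For the 118Q effect (24 genes) limma gave 150 genes with the lowest 60% removed, 48 with arrays centred on their median, 43 with quantile normalization, 200 with an intensity trend, 3134 with array weights, whose estimate did not converge, 0 in a fit of only the groups compared, 5 with the replicate block, 391 at an adjusted p below 0.1, 315 at an unadjusted p below 0.05 with a fold of 1.5, 7 with the gene span trend removed, 0 with the 18S covariate, 3 without wild type replicate 3 of both lines, and 4 to 707 with an array left out. Its lists (16) were 0 with an estimated correlation and 9 with the 18S covariate; disease-associated microglia (adjusted p = 0.161) and immediate early genes (0.0998) missed with the lowest 60% removed, and array weights ended these (0.0631 and 0.223) and the antioxidant (0.0891) and glucocorticoid (0.0906) calls. The antioxidant list also missed with the mean of a gene's probe sets (0.113), and without wild type replicate 3 of both lines the immediate early (0.276) and glucocorticoid (0.0696) lists missed. For the 11Q effect (0 genes by limma, 536 at an unadjusted p below 0.05) 1 gene was called in a fit of only the groups compared and 100 at an unadjusted p below 0.05 with a fold of 1.5. Its lists (7) were 4 with arrays centred on their median, 4 with quantile normalization, 0 with an estimated correlation, 0 by fry, 14 with the 18S covariate, 4 without wild type replicate 3 of both lines, and 4 to 7 with an array left out. For the difference of effects (0 genes by limma, 1392 at an unadjusted p below 0.05) array weights gave 614, an unadjusted p below 0.05 with a fold of 1.5 gave 440, and leaving out an array 0 to 12. Its lists (20) were 0 with an estimated correlation, 3 by fry and 9 with the 18S covariate. Knockin against knockin (1733 genes) gave 6114 with array weights, 2892 at an adjusted p below 0.1, 870 at an unadjusted p below 0.05 with a fold of 1.5, 832 with the gene span trend removed, 0 with the 18S covariate and 319 to 2274 with an array left out. Wild type against wild type (0 genes by limma, 378 at an unadjusted p below 0.05) gave 2 with array weights, 32 at an unadjusted p below 0.05 with a fold of 1.5, 1 with Ttr, 1 with 18S as covariate, 1 without wild type replicate 3 of both lines, and 0 to 1 with an array left out.

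With the 18S covariate the 118Q effect turned to 0.059 for Cacna1a, 0.076 for Gad1, 0.0204 for Slc32a1, 0.13 for Abcb1a, 0.0118 for Pclo, -0.0888 for Mobp and -0.27 for Per1, and knockin against knockin to -0.0758 for Nr4a3 and 0.47 for F2r; the cause was not tested. The sources used here do not say whether the replicate numbers pair the mice. Deviations of mice of the same number and line correlated at -0.171 to 0.193, so the values show no clear pairing within a line. Across lines, wild type replicates 3 stood apart together: their deviations correlated at 0.447, the highest of the pairs from different groups, and their values at 0.995, higher than with any array of their own groups (0.991 at most), and they had the lowest differences between the 5' and 3' probe sets of the dap control (-2.95 and -3.05). Without both, Fgf14 missed in the 118Q effect (adjusted p = 0.0757). A block of replicate within line could not be fitted for knockin against knockin or wild type against wild type, and the Xist covariate was not run because Xist spanned 0.665 log2 units. No depth is defined for these arrays; genes near background, under the filter, were tested only in the fits with no filter.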

Other observations

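The tests of genes on chromosome 8 were chosen only after the result was seen.

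Glial and other cell lists not described above did not pass in the 118Q knockin. Oligodendrocyte and myelin genes had a median of 0.21 (22 of 26 above 0, adjusted p = 0.115), and Mobp, a myelin protein, differed by 0.66 (0.40 without wild type replicate 3). Astrocyte and Bergmann glia markers had a median of 0.09 (adjusted p = 0.978) and oligodendrocyte precursor markers of -0.12 (adjusted p = 0.13), with Ptprz1, which both lists hold, at -0.55. Markers of granule cells, the most numerous neurons of the cerebellum, had a median of -0.03 (adjusted p = 0.102), and markers of the cerebellar nuclei and brainstem of -0.10 (adjusted p = 0.0952), with Nefh, the heavy neurofilament, at -0.63. Choroid plexus markers had a median of -0.22 (adjusted p = 0.13) and Ace differed by -0.35 (-0.12 without wild type replicate 1). Blood cell genes had a median of 0.27 over 7 measured members (adjusted p = 0.121), 4 of them higher when adjusted over the list alone, with S100a9, a neutrophil protein, at 1.07.

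Pathways of protein turnover and growth did not pass either. The endoplasmic reticulum stress response had a median of -0.04 (adjusted p = 0.0548), and 3 members were lower when adjusted over the list alone; Hsp90b1, a chaperone of that compartment, differed by -0.50. Lysosome genes had a median of 0.05 (adjusted p = 0.611), with 2 higher when adjusted over the list alone and Neu1, a sialidase, at 0.49. Autophagy genes (0.06, adjusted p = 0.828), with Wdfy3 at -0.53, proteasome subunits (0.07, adjusted p = 0.29), with Psme1 at 0.29, and p53 and cell death genes (0.05, adjusted p = 0.978), with Bcl2l11, a promoter of apoptosis, at 0.86, did not pass. Cholesterol biosynthesis (0.05, adjusted p = 0.837), mitotic cell cycle genes (0.08, adjusted p = 0.978) and circadian clock genes (0.15, adjusted p = 0.345) did not pass. By fry's test for change in either direction the granule cell (adjusted p = 0.0135), endoplasmic reticulum stress (0.0127), lysosome (0.00403) and autophagy (0.023) lists passed. Of the sex-linked genes, which were described and not tested, Kdm5c, on the X chromosome, differed by -0.37 (adjusted p = 0.197; -0.25 without wild type replicate 3).

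Genes on chromosome 8 were frequent among the smallest p-values of the 11Q effect: of the 11 genes at an unadjusted p below 0.001, 7 lay there, where its 5.40% of genes would give 0.594. These genes are Zfp869, Mau2, Slc25a42, Comp, Mri1, Gadd45gip1 and Lpcat2, within 131 tested genes of Cacna1a. A donor chromosome segment kept around the knockin allele stays open. Among the other 676 genes of the chromosome, the 52 at an unadjusted p below 0.05 lay at a median distance of 88 genes from Cacna1a, against 179.5 for the rest, but an exact permutation test over all 676 rotations of the p-values along the chromosome, which keeps neighbours together, gave p = 0.275, two-sided, where a rank test that takes genes as independent had given 0.00019. In the 118Q line the 118 such genes lay at a median distance of 141 against 177 (exact permutation test, p = 0.071). Within 25, 50, 100 and 200 genes on each side, 12 of 51, 14 of 101, 32 of 201 and 48 of 401 genes had an unadjusted p below 0.05 in the 11Q line, where chance gives 2.55, 5.05, 10.1 and 20.1, and 13, 17, 42 and 76 in the 118Q line, where the share over all genes, 18.7%, would give 9.52, 18.9, 37.5 and 74.8. An effect of the allele that both lines share stays open too: 2 of the 7, Mau2 and Slc25a42, moved the same way in the 118Q line at an unadjusted p below 0.05. Comp read 4.52 to 4.68 in the 11Q knockin and 1.76 to 2.29 in its littermates. It read 2.09, 4.29 and 4.41 in the wild types of the 118Q line, so a high Comp reading also occurs without the allele. Mau2, Slc25a42, Gadd45gip1 and Lpcat2 did not reach the 11Q knockin's range in those wild types, though Mau2 came near it (5.52 at most, against 5.55 to 5.87). Mri1 did reach it (4.35, 3.90 and 3.93, against 3.33 to 3.93). Sequence differences under single probe sets stay open as well, since 2 of the 7 genes have another probe set above the filter and 1, Mau2, has one that moved the same way at an unadjusted p below 0.05. The other Gadd45gip1 probe set differed by 0.29, on the other side. No genotype of these segments is given in the sources used here.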
